A study of Mus musculus with 6 samples.

How the data were processed

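The series holds 6 arrays of total RNA from resting B cells of the spleen of Sirt1 conditional knockout mice, 3 labelled control and 3 labelled tamoxifen, treated for 5 days per the labels' protocols. Cells were prepared by magnetic-activated cell sorting and RNA was converted to biotin-labelled sense cDNA with GeneChip Whole Transcript kits, per the labels' protocols. The deposited values were made by the authors with RMA in Affymetrix Expression Console, per the submitters' processing notes, which give no version. RMA corrects background, quantile-normalizes arrays and summarizes probes. It compresses differences between dim probe sets and makes array distributions alike, so a change shared by most transcripts would not be seen. The deposited values were treated as log2, because their range of 1.28 to 13.1 and the use of RMA fit that scale. The log base itself is not stated in the sources used here. The genome build is not given in the sources used here either, so no coordinates are given.

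The table has 41345 probe sets. In GEO's platform annotation, 25341 had an entry, of which 23521 named 1 gene and 1820 several, and 16004 had none. Of those naming 1 gene, 23328 were matched by Entrez identifier to a RefSeq gene table (assembly GRCm38.p6, used for names), and 0 symbols changed. The brightest probe set, by its mean over all arrays, stood for each gene, which mattered for 1082 genes with more than 1 probe set. This left 22180 genes, and no filter on dim genes was applied. Probe sets naming no gene or several stayed out of the main comparison and were tested as an alternative. No Cd19 probe set was named, so Cd19 was not analysed here. Files of unprocessed array scans were not used here, so background and detection could not be assessed.

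Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, without trend or robust priors, two-sided, Benjamini-Hochberg adjusted, threshold 0.05). A difference is tamoxifen minus control in log2, with moderated SE and 95% confidence interval. Sirt1 was also compared by an exact two-sided permutation test. The model was tested on simulated data with 200 of 22180 genes changed by 1.5, 2 or 4-fold and noise independent between genes. It recovered 99.5% of those changed 4-fold. Gene lists with at least 5 measured genes were tested with limma's camera at its preset correlation of 0.01, adjusted over the 41 lists tested. Camera with an estimated correlation and fry were checks. Fry asks whether a list's genes move one way, and its mixed form whether they move in any direction, without comparing them with other genes.

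The comparisons, the named genes, the lists and most alternatives were fixed before the data were examined. The rule named Sirt1 and Cd19, then up to 12 genes per direction past the threshold by size. Places left were filled with genes of smallest unadjusted p whose groups did not overlap, said not to have passed. Unnamed gene models, small RNAs, antigen receptor segments and chemoreceptor genes were skipped there. For each list described, up to 4 genes of smallest p could be named. Of the 44 lists, 3 had under 5 measured genes. The lists were CD19 coreceptor and B cell receptor signalling, sirtuins and NAD metabolism, p53 targets, NF-kB targets, FOXO targets, immediate early and dissociation stress, B cell activation, cell cycle, apoptosis, oxidative phosphorylation, glycolysis, cholesterol and fatty acid synthesis, and fatty acid oxidation with PGC-1/PPAR genes. Others were antioxidant and NRF2, unfolded protein response, autophagy and lysosome, circadian clock, interferon-stimulated, oestrogen receptor and tamoxifen-related, antigen presentation, B cell homing, histone and DNA modifying enzymes, B cell transcription factors, B cell cytokines, ribosomal proteins, histones and 3 immunoglobulin lists. Marker lists covered follicular, marginal zone, transitional, B-1, germinal centre and plasma cells, T, NK, monocyte and macrophage, dendritic, neutrophil, erythroid, megakaryocyte, stromal and sex-linked genes. They were written from general knowledge, not from these samples.

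Alternatives were quantile normalization, median centring, leaving out dim genes, trend and robust priors (statmod 1.5.0), array weights, the replicate number as a block, leaving out each array, the mean of a gene's probe sets, all probe sets, an unmoderated test, other thresholds and limma's treat. Covariates for the sex pattern and for erythroid content were added after seeing the data. The labels give no scan date or batch. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.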

Results

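The data comprised 6 Affymetrix arrays hybridised with total RNA from resting B cells of the mouse spleen, prepared by magnetic-activated cell sorting from animals carrying a conditional Sirt1 allele. Sirt1 encodes an NAD-dependent protein deacetylase. In the labels, 3 arrays were controls and 3 followed 5 days of tamoxifen, a drug widely used to switch on Cre recombinases fused to an oestrogen receptor domain. The labels also call the tamoxifen group a CD19 deletion. They do not say whether this means loss of the Cd19 gene, which encodes a B cell coreceptor, or loss of Sirt1 in CD19-positive cells. The deposited values, read as log2, had medians of 4.68 to 4.78 per array, and the number of arrays limits the precision. Pearson's r between arrays lay between 0.988 and 0.994 across genes, which are not independent replicates. The B cell genes Cd79a and Ighm, members of lists fixed beforehand, averaged 12.1 and 12.7 in the controls, with differences of −0.017 and 0.047. Xist, the RNA of the inactive X chromosome, read 10 in control replicate 1 and 10.2 in tamoxifen replicate 1. It read 3.04 to 3.57 in the remaining arrays, in which the Y-linked genes Eif2s3y, Kdm5d and Uty read from 6.90 to 8.58. The groups were thus alike in the number of arrays with each pattern. The labels do not say whether replicates came from separate animals. In each group replicate 1 differed from the others in this sex pattern, so a group cannot come from a single animal. The p-values measure the spread between these samples, which includes this sex difference and may be partly technical.

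The question put to the target gene was whether its RNA differed after tamoxifen. Sirt1 RNA averaged 8.21 ± 0.0047 (SD, n = 3) in the controls and 7.90 ± 0.13 (SD, n = 3) after tamoxifen. The difference was −0.31 (SE 0.10, 95% confidence interval −0.54 to −0.085), or 19.5% lower (interval 5.72% to 31.2%). All 3 tamoxifen arrays lay below all 3 controls. The exact two-sided permutation test gave p = 0.1, the smallest p that the 20 assignments of the arrays allow. The limma model gave an unadjusted p of 0.0126, rank 196 among 22180 genes, and an adjusted p of 0.997, so Sirt1 did not pass the test across all genes. A single probe set names Sirt1, and whether its probes lie in the deleted part is not known, so its level does not measure how complete the deletion was. In the annotation used, 0 probe sets name Cd19, which was not analysed here.

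The comparison across all genes asked which transcripts differed between tamoxifen and control B cells. The largest differences were those of Hspa1a and Hspa1b, the stress-inducible members of the HSP70 chaperone family. Hspa1a averaged 5.82 ± 0.37 (SD, n = 3) in the controls and 7.80 ± 0.26 (SD, n = 3) after tamoxifen, 3.95-fold higher (log2 1.98, SE 0.20). Hspa1b averaged 6.22 ± 0.43 (SD, n = 3) and 8.08 ± 0.21 (SD, n = 3), 3.61-fold higher (log2 1.85, SE 0.20). All 3 tamoxifen arrays lay above all controls for each gene, yet limma's adjusted p was 0.0744 for Hspa1a and 0.0917 for Hspa1b. The pair is nearly identical in sequence, so the split of signal between its members is uncertain. Without control replicate 1, both passed limma's test, with adjusted p = 0.0119 for Hspa1a and 0.00982 for Hspa1b. Leaving out control replicate 2 instead gave adjusted p = 0.747 and 0.748. In all, limma called 0 of 22180 genes, with 901 at an unadjusted p under 0.05 (467 higher, 434 lower) where chance would give 1109. A test with unmoderated variances also called 0 genes, with 902 at an unadjusted p under 0.05. The groups did not overlap for 1949 genes, or 8.79%, and chance gives 10%. With a fold of at least 1.5 as well, 33 genes had an unadjusted p under 0.05, 16 higher and 17 lower. The 95% interval lay inside 2-fold in either direction for 99.2% of genes. In simulated data of the same size, with 200 genes changed and noise independent between genes, the model recovered 59% of genes changed 1.5-fold and 97.5% of those changed 2-fold. With fewer changed genes the adjusted threshold is stricter, and Hspa1a, 3.95-fold higher, was not called here. These shares therefore do not show that few 2-fold changes were missed.

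**Figure D1:**
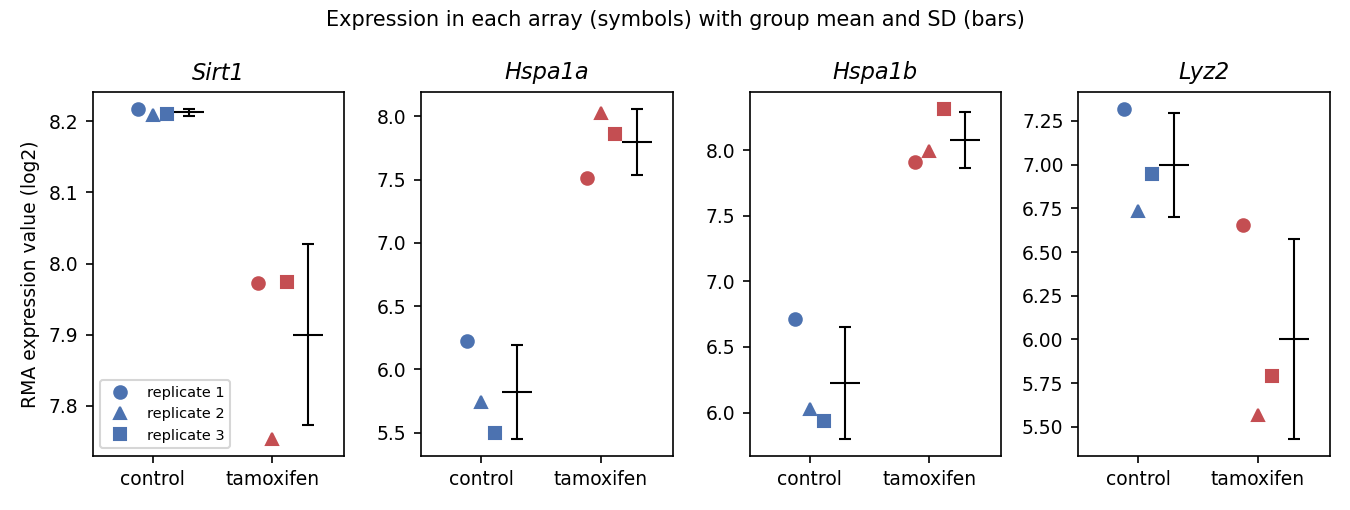
Log2 expression values (vertical axis) of Sirt1, Hspa1a, Hspa1b and Lyz2 in the control and tamoxifen groups. Symbols mark the 3 replicates and bars the group mean and SD. In each panel the groups do not overlap, and the difference ranged from −0.997 for Lyz2 to 1.98 for Hspa1a.

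None of the following genes passed the test across all genes. They were named by the smallest unadjusted p among genes whose groups did not overlap. After Hspa1a and Hspa1b, the higher side was led by Sprr2d, a small proline-rich protein of the cornified envelope (difference 0.84, SE 0.14), and Csta2, of the stefin A family of cysteine protease inhibitors (0.66, SE 0.12). Bex3 (0.58), Ssxb6 (0.50), Selp, which encodes the adhesion receptor P-selectin (0.46), and Fxyd2, a regulator of the sodium pump (0.45), followed. Kif7, a kinesin of hedgehog signalling (0.41), Nrip3 (0.40), Myrip (0.38) and Frg2f1 (0.37) completed the 12. On the lower side stood Polr2l, a small subunit shared by RNA polymerases (−0.68, SE 0.13), and Ifitm6, an interferon-induced transmembrane protein (−0.57, SE 0.14). The cytokine gene Il1b differed by −0.52, Tcp10a by −0.52 and Hp, the gene of haptoglobin, by −0.47. Haao, an enzyme of the kynurenine route to NAD, differed by −0.42, Scml4 by −0.42 and Carns1, the carnosine synthase gene, by −0.41. Wwc2 and the fatty acid receptor gene Ffar1 each differed by −0.41, and Gpr35 and Atp6v1fnb each by −0.40. Of the 12 higher genes, 7 lay below the median level of all genes, 4.85, as did 2 of the 12 lower. Only 3 genes differed by 2-fold or more, namely Hspa1a, Hspa1b and Sirpb1c, a signal-regulatory protein gene (−1.11, SE 0.31), named after its value was seen. Gene models without a name, small RNAs, antigen receptor segments and chemoreceptor genes were not named. They made up 243 of the 901 genes at an unadjusted p under 0.05, 132 higher and 111 lower.

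**Figure D2:**
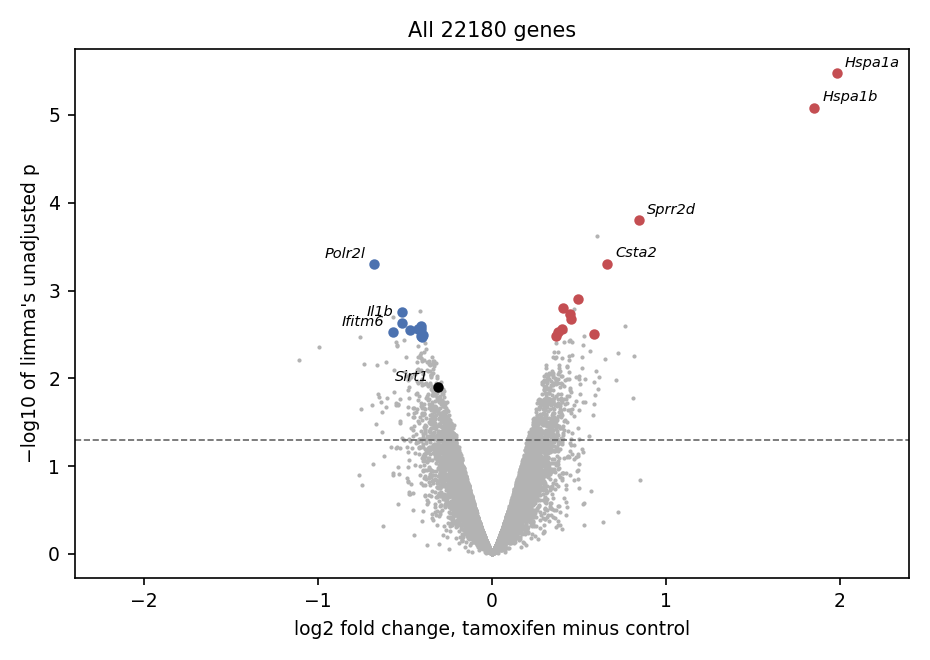
Log2 fold change, tamoxifen minus control (horizontal axis), against −log10 of limma's unadjusted p (vertical axis) for all 22180 genes. Red and blue points are the 12 named genes on each side, the black point is Sirt1, and the dashed line marks an unadjusted p of 0.05. Hspa1a and Hspa1b stand apart at 1.98 and 1.85.

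Of 41 gene lists tested with camera at its preset correlation, 13 shifted, 7 higher and 6 lower. With an estimated correlation 0 lists shifted (smallest adjusted p = 0.663, with 3 lists at an unadjusted p under 0.05), and fry called 0 (smallest adjusted p = 0.712, and 0.151 for change in either direction). Among the 13 lists the estimate ran from −0.0119 (homing) to 0.922 (erythroid), against the preset of 0.01. For the transitional, follicular and homing lists it was near the preset (0.0125, 0.0117 and −0.0119). Camera's unadjusted p still rose there (0.0032 to 0.044, 0.00472 to 0.0485 and 0.0065 to 0.0428), so correlation alone does not explain those lost calls. The 13 lists hold 285 different genes, of which limma called 0, either over all genes or adjusted over the list alone, and 21 had an unadjusted p under 0.05 (12 higher, 9 lower). Their members are therefore given as values.

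The 6 lists that shifted lower cover B cell signalling, B cell subsets, antigen presentation, trafficking and FOXO targets. In the CD19 coreceptor and B cell receptor signalling list, 22 of 26 genes lay lower after tamoxifen, with a median difference of −0.065 (camera adjusted p = 0.00714, and adjusted p = 0.738 with an estimated correlation). They included the kinases Prkcb (−0.22) and Syk (−0.21), the adaptor Pik3ap1 (−0.17) and the inhibitory coreceptor Cd22 (−0.17). Of the FOXO target genes, 13 of 16 lay lower, median −0.13, among them the repressor Bcl6 (−0.35), the cyclin Ccng2 (−0.31), the trafficking regulator Klf2 (−0.19) and the cell cycle inhibitor Cdkn1b (−0.19). The adjusted p was 0.00714, and adjusted p = 0.738 with an estimated correlation. Transitional and immature B cell markers had a median of −0.11, with 10 of 15 lower (camera adjusted p = 0.0164, and adjusted p = 0.663 with an estimated correlation). The transcription factors Myb (−0.56) and Sox4 (−0.32) and the surface receptor Cd93 (−0.42) each had an unadjusted p under 0.05. With the mean of its probe sets in place of the brightest, Myb stood at −0.17. Follicular B cell markers lay lower in 8 of 10 genes, median −0.15, among them the complement regulator Cd55 (−0.32) and the low-affinity IgE receptor Fcer2a (−0.23). Camera gave an adjusted p of 0.0212, and adjusted p = 0.663 with an estimated correlation. In the antigen presentation list 14 of 18 genes lay lower, median −0.072 (camera adjusted p = 0.0212, and adjusted p = 0.738 with an estimated correlation), among them H2-DMb1 (−0.41) and H2-Ob (−0.31), which act in class II peptide loading, and the peptide transporter Tap2 (−0.37). B cell homing and adhesion genes had a median of −0.10, with 11 of 17 lower, including the chemokine receptor Ccr6 (−0.44) and the integrins Itga4 (−0.27) and Itgb7 (−0.21). Camera gave an adjusted p of 0.0242, and adjusted p = 0.663 with an estimated correlation. Without tamoxifen replicate 2 all 6 calls were lost (adjusted p from 0.175 to 0.43). The antigen presentation median became 0.0010, while the others stayed lower, at −0.048 (CD19 and B cell receptor signalling), −0.090 (FOXO), −0.085 (transitional), −0.089 (follicular) and −0.078 (homing). Without control replicate 1, calls were also lost for antigen presentation (median −0.022, adjusted p = 0.189), homing (−0.069, 0.0623) and transitional lists (−0.17, 0.0655). The FOXO (−0.086, 0.0527) and homing lists (−0.11, 0.0816) lost theirs without control replicate 3, while the CD19 list went to −0.11 there and kept its call. Single arrays also weighed on several of these genes. Without tamoxifen replicate 3 the difference was −0.11 for Ccr6, −0.15 for Itga4, −0.096 for Klf2 and −0.37 for Myb. Without control replicate 3 it was −0.14 for Syk and −0.20 for Cd55, and without tamoxifen replicate 2 −0.21 for Bcl6, −0.12 for Cdkn1b and −0.15 for Fcer2a. Leaving out tamoxifen replicate 1 gave −0.47 for Ccng2 and −0.30 for Cdkn1b.

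Among the lists that shifted higher, ribosomal protein genes had a median difference of 0.13, with 57 of 67 genes higher (camera adjusted p = 7.08e-06, and adjusted p = 0.738 with an estimated correlation), with Rps18 (0.45) and Rps26 (0.27) higher and Rps20 (−0.58) lower. Immunoglobulin light chain variable segments lay higher in 13 of 14 genes, median 0.24, among them Igkv4-59 (0.47) and Igkv8-30 (0.26). Camera gave an adjusted p of 0.000618, and adjusted p = 0.738 with an estimated correlation. Such segments share sequence, so signal between them is not fully separable. Interferon-stimulated genes had a median of 0.17, with 17 of 22 higher (camera adjusted p = 0.00164, and adjusted p = 0.738 with an estimated correlation), including the master regulator Irf7 (0.56), Oasl1 (0.52), Usp18 (0.44) and Ifit1 (0.38). Genes of oxidative phosphorylation lay higher in 22 of 28 cases, median 0.10 (camera adjusted p = 0.00714, and adjusted p = 0.738 with an estimated correlation), among them the ATP synthase gene Atp5o (0.43) and the complex I gene Ndufa2 (0.41). Antioxidant and NRF2 genes lay higher in 16 of 17 cases, median 0.073, including thioredoxin, Txn1 (0.37), and Nfe2l2, the gene of NRF2 itself (0.28). Camera gave an adjusted p of 0.0497, and adjusted p = 0.738 with an estimated correlation. The ribosomal protein list kept its call without each single array (adjusted p at most 0.0303), with a median of 0.078 without control replicate 3, 0.091 without tamoxifen replicate 3 and 0.22 without control replicate 1. Relative to the control mean it stood at 0.18 in control replicate 1, level with tamoxifen replicates 1 and 3 (0.19 each), and at 0.021 in tamoxifen replicate 2. Without control replicate 1 the medians of the other lists here grew too, to 0.40 (segments), 0.32 (interferon), 0.18 (oxidative phosphorylation) and 0.15 (antioxidant). The segments, interferon, oxidative phosphorylation and antioxidant lists lost theirs without tamoxifen replicate 1 (medians 0.15, 0.11, 0.067 and 0.070, adjusted p = 0.0794, 0.275, 0.277 and 0.213) and without control replicate 2 (medians 0.14, 0.062, 0.038 and 0.077, adjusted p = 0.0567, 0.207, 0.183 and 0.159). Oxidative phosphorylation and antioxidant lists also did so without control replicate 3 (medians 0.068 and 0.022, adjusted p = 0.11 and 0.389), and the antioxidant list without tamoxifen replicate 2 (0.063, 0.231). Without control replicate 2 the differences of Irf7, Oasl1 and Usp18 were 0.29, 0.34 and 0.18. Without control replicate 3 Ndufa2 stood at 0.25 and Igkv8-30 at 0.13, and without control replicate 1 Ndufa2 stood at 0.61. Leaving out tamoxifen replicate 3 gave 0.11 for Nfe2l2 and −0.26 for Rps20, tamoxifen replicate 2 −0.88 for Rps20, and tamoxifen replicate 1 0.17 for Igkv8-30.

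Cell cycle genes and erythroid markers, the remaining lists called higher, differed widely between the tamoxifen arrays. The cell cycle median was 0.20, with 28 of 29 genes higher (camera adjusted p = 0.00164, and adjusted p = 0.793 with an estimated correlation), and by p the first were the ubiquitin-conjugating enzyme Ube2c (0.45), thymidylate synthase, Tyms (0.37), and the replication helicase subunit Mcm7 (0.25). Relative to the control mean, the list's median was 0.45 in tamoxifen replicate 1, 0.62 in replicate 2 and −0.42 in replicate 3, against −0.093 to 0.15 in the controls. All 15 erythroid markers lay higher, median 0.30, with Tfrc, the transferrin receptor gene, at 0.37 and the transcription factor gene Klf1 at 0.43. Camera gave an adjusted p of 0.0497, and adjusted p = 0.848 with an estimated correlation. This list's median stood at 1.58 in tamoxifen replicate 2, at 0.079 in replicate 1 and at −0.54 in replicate 3, against −0.52 to 0.31 in the controls. Slc4a1, the red cell anion exchanger, read 8.80 in tamoxifen replicate 2 and 4.87 in replicate 3. Without tamoxifen replicate 2 the erythroid median turned to −0.24 (adjusted p = 0.0455) and the cell cycle median was 0.0071 (adjusted p = 0.992), with Tfrc at −0.092, Klf1 at 0.11, Tyms at 0.25 and Mcm7 at 0.13. Without tamoxifen replicate 3 these genes stood at 0.76, 0.75, 0.60 and 0.44, and the erythroid and cell cycle medians at 0.85 and 0.48. Without control replicate 2 the erythroid median was 0.47. Without tamoxifen replicate 1 the calls were also lost (cell cycle 0.079, adjusted p = 0.303, and erythroid 0.42, adjusted p = 0.0794), as was the erythroid call without control replicate 3 (0.042, adjusted p = 0.702), with Klf1 at 0.28.

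**Figure D3:**
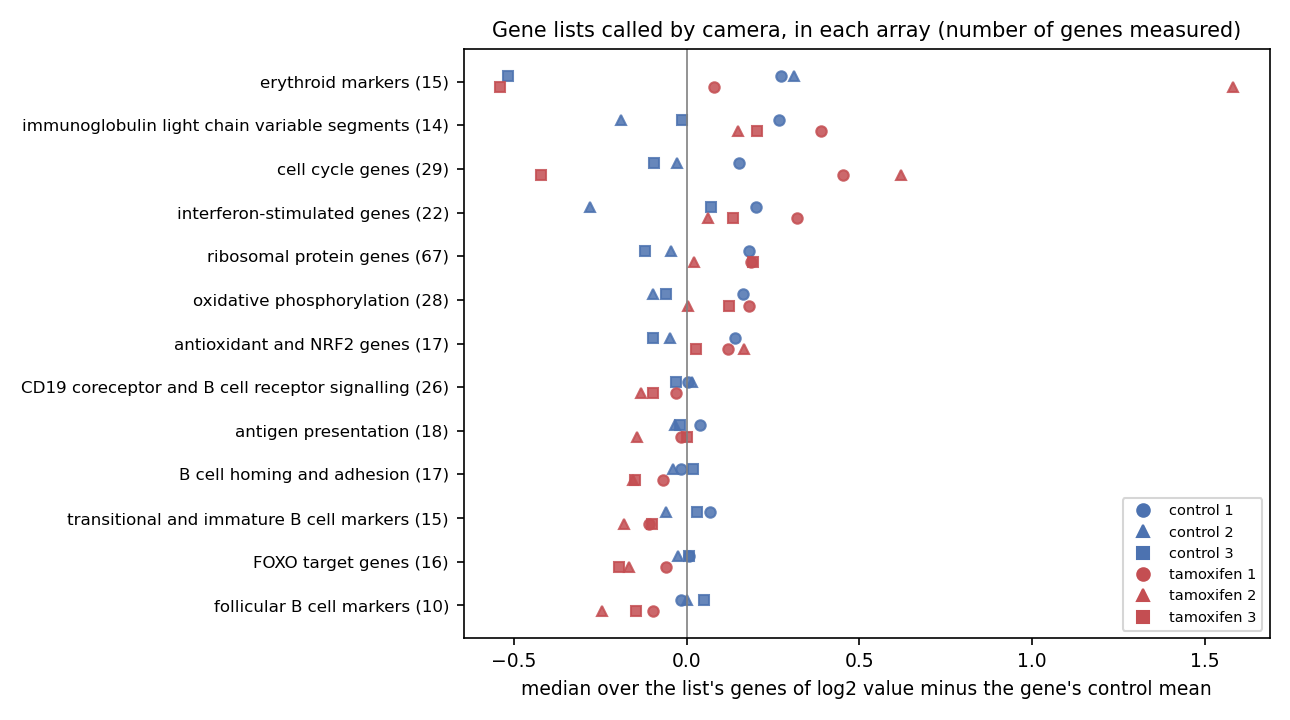
Median, over the genes of each of the 13 lists called by camera, of the log2 value minus the gene's control mean (horizontal axis), for each array. Blue marks control and red tamoxifen arrays, and shapes mark the replicate number. Erythroid markers range from −0.54 to 1.58 between tamoxifen arrays, more widely than the other lists.

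Camera did not call the following lists of metabolism, stress and regulatory pathways. The median difference was −0.027 for sirtuins and NAD metabolism (20 genes, adjusted p = 0.313), −0.034 for p53 targets (21 genes, 0.82), −0.026 for NF-kB targets (23 genes, 0.899) and −0.016 for histone and DNA modifying enzymes (23 genes, 0.226). Medians were −0.035 for fatty acid oxidation and PGC-1/PPAR genes (18 genes, 0.226), −0.011 for the circadian clock (17 genes, 0.87), 0.063 for autophagy and lysosome (20 genes, 0.226) and −0.040 for apoptosis regulators (22 genes, 0.535). Glycolysis had a median of 0.039 (16 genes, 0.684), cholesterol and fatty acid synthesis 0.086 (19 genes, 17 of them higher, 0.0675) and the unfolded protein response 0.018 (19 genes, 0.238). Genes related to the oestrogen receptor and tamoxifen had a median of 0.071 (17 genes, 0.34). Immediate early and dissociation stress genes had a median of 0.0055 (28 genes, 0.226), and only Hspa1a and Hspa1b passed when adjusted over the list alone.

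Lists of B cell states other than those above were not called by camera either. Medians were −0.035 for activation genes (20 genes, adjusted p = 0.446), 0.060 for marginal zone markers (18 genes, 0.551), 0.036 for B-1 and age-associated markers (14 genes, 0.705) and 0.11 for germinal centre markers (12 genes, 0.82). Plasma cell markers had a median of 0.033 (15 genes, 0.607), B cell transcription factors −0.048 (27 genes, 0.28) and B cell cytokines with their receptors −0.052 (27 genes, 0.103). The heavy chain variable segments (3 genes, median 0.16) and immunoglobulin constant genes (2 genes, median 0.15) were too few to test, and 0 genes of the histone list were measured.

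Markers of other spleen cells were measured to see what the sorted samples held, and none of these lists apart from the erythroid one was called. Lyz2, the lysozyme gene of macrophages and granulocytes, averaged 6.999 ± 0.298 (SD, n = 3) in the controls and 6.003 ± 0.574 (SD, n = 3) after tamoxifen, a difference of −0.997 (SE 0.26). The integrin gene Itgam differed by −0.64 (−0.41 without tamoxifen replicate 3) and the monocyte chemokine receptor gene Ccr2 by −0.34. For these 3 genes limma's adjusted p was 0.997. The whole monocyte and macrophage list had a median of −0.021 (24 genes, camera adjusted p = 0.535), with 11 genes higher and 13 lower. Fcgr1, next by p after those named, was higher (0.19). Medians were −0.074 for T cell markers (20 genes, 0.0666), −0.058 for NK cell and innate lymphoid markers (15 genes, 0.292), −0.035 for dendritic cell markers (16 genes, 0.82) and −0.0097 for neutrophil and granulocyte markers (22 genes, 0.891). They were −0.041 for megakaryocyte and platelet markers (13 genes, 0.82), of which Selp passed when adjusted over the list alone, 0.031 for stromal and endothelial markers (18 genes, 0.763) and −0.13 for sex-linked genes (6 genes, 0.623). No other gene of the lists not called passed limma's test over all genes or adjusted over the list alone. Mean and median differed in sign for B-1 (mean −0.051), stromal (−0.019), neutrophil (0.015) and NF-kB (0.011) lists. For the first 2 of these camera's direction followed the mean, and for the others the median.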

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

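The sex covariate and the erythroid covariate were chosen after the data were seen. Sirt1 kept its direction and stayed short of the threshold in all 15 alternatives, with differences from −0.35 to −0.24. The number of genes called was 2 (Hspa1a and Hspa1b) with trend and robust priors, with array weights and at an adjusted p under 0.1. It ranged from 0 to 2 on leaving out each array, with 2 only without control replicate 1. Other alternatives called 0, all 41345 probe sets included (limma, 1651 at an unadjusted p under 0.05). None of 17824 probe sets without a single gene name passed among themselves (smallest adjusted p = 0.392). The 13 shifted lists became 0 with an estimated correlation and 0 with fry. Leaving out each array gave 7 to 15 lists, 7 without tamoxifen replicate 1 and 7 without tamoxifen replicate 2. Of the latter, 5 were among the 13, with 1 reversed. The erythroid covariate left 9 lists, 8 of them among the 13. It ended the cell cycle (0.088, adjusted p = 0.117), antioxidant (0.063, 0.12), antigen presentation (−0.048, 0.0967) and follicular calls (−0.13, 0.0904). The end of the erythroid call (0.067, 0.745) was fixed in advance, because the covariate is the mean of that list's own genes. The mean of a gene's probe sets left 9, all among the 13, without the follicular (−0.14, 0.0545), transitional (−0.11, 0.0545), erythroid (0.30, 0.0545) and antioxidant lists (0.073, 0.0666). The erythroid call was also lost with quantile normalization (0.34, 0.0807) and the sex covariate (0.30, 0.0808), and the antioxidant call with median centring (0.084, 0.058). The sex covariate gave 12 lists and 0 genes (limma, 1094 at an unadjusted p under 0.05, smallest adjusted p = 0.192). The replicate number as a block gave 14 lists and 0 genes (limma, 1158 at an unadjusted p under 0.05, smallest adjusted p = 0.436). The numbers were not taken as pairs in the main comparison, because no label says that they mark a shared animal, litter or day. Same-numbered arrays deviated together with r of 0.32, 0.28 and 0.09, which leaves pairing open. By these deviations from the group means, each array was nearest its own number in the other group. The cause of these changes was not tested, and the array scans that would give signal over background were not used here.

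Lists not called passed in some settings. T cell markers did so with quantile normalization (adjusted p = 0.0433), the replicate block (0.0473) and without control or tamoxifen replicate 2 (0.0265 and 0.0403). Cholesterol and fatty acid synthesis did so with quantile normalization (0.0285), without dim genes (0.0321), with the erythroid covariate (0.0182) and without tamoxifen replicate 2 (0.000262). On leaving out each array its median ranged from 0.039 to 0.15, with camera adjusted p up to 0.754. Without control replicate 2, immediate early (0.00114), NK cell (0.0293) and fatty acid oxidation (0.0435) lists passed. Marginal zone markers passed without control replicate 1 (0.0232) or tamoxifen replicate 3 (0.0442), cytokines without the latter (0.0131) and monocyte markers without control replicate 3 (0.0339).

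Of 613 values of list medians under alternatives, 52 had the other sign. With quantile normalization these were p53 targets (0.010), NF-kB targets (0.011), monocyte (0.0064) and megakaryocyte markers (0.0032). With median centring they were the circadian clock (0.00048) and neutrophil markers (0.0013). Without dim genes they were the oestrogen receptor (−0.0017), B-1 (−0.0047) and stromal lists (−0.0056). Array weights turned NF-kB targets (0.017) and monocyte markers (0.0086), and the erythroid covariate plasma cell (−0.042) and neutrophil markers (0.0078). On leaving out each array, medians ranged from −0.24 to 0.85 for erythroid markers, −0.079 to 0.0010 for antigen presentation, −0.071 to 0.0086 for sirtuins, −0.079 to 0.023 for p53 and −0.029 to 0.079 for NF-kB targets. Ranges were −0.086 to 0.16 for immediate early genes, −0.0036 to 0.094 for glycolysis, −0.012 to 0.065 for the unfolded protein response and −0.032 to 0.024 for the circadian clock. They were −0.065 to 0.19 for marginal zone, −0.035 to 0.043 for B-1, −0.14 to 0.17 for germinal centre and −0.061 to 0.12 for plasma cell markers. Other cell types ranged from −0.11 to 0.0062 (T cell), −0.14 to 0.075 (NK cell), −0.12 to 0.074 (monocyte), −0.064 to 0.013 (dendritic) and −0.057 to 0.0073 (neutrophil). Megakaryocyte markers ranged from −0.094 to 0.036, stromal from −0.017 to 0.041 and sex-linked genes from −0.98 to 0.62. Without a change of sign, activation genes ranged from −0.051 to −0.0048, autophagy from 0.021 to 0.088 and histone and DNA modifying enzymes from −0.054 to −0.020. Among 79 single genes, Trim10 (−0.22 to 0.83), Tfrc (−0.092 to 0.76) and Nqo1 (−0.00070 to 0.30) changed sign, each without tamoxifen replicate 2. With the mean of a gene's probe sets Kif7 stood at 0.25, Myb at −0.17, Rps18 at 0.24 and Rps20 at −0.23, and with the erythroid covariate Klf1 stood at 0.26 and Tfrc at 0.17.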

Other observations

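The tests on immediate early genes and on erythroid content, and the repeats of list percentiles without each array, were chosen after the results they bear on had been seen. Once Hspa1a and Hspa1b stood out, 8 further chaperones were examined, so these were chosen after values were seen. The co-chaperone Dnajb1 differed by 0.51 (SE 0.17, and 0.32 without tamoxifen replicate 3), the disaggregase partner Hsph1 by 0.50 (0.33 without it), the mitochondrial chaperonins Hspe1 and Hspd1 by 0.39 and 0.33, Hspa8 by 0.34 and Hsp90aa1 by 0.33. These 6 had a limma p under 0.05 when adjusted over those 8 genes alone, and none over all genes. Hspb1 (0.16, and 0.031 without control replicate 3) and Bag3 (0.13, and 0.048 without control replicate 2) did not. Because the 8 were picked after values were seen, an adjustment over them alone decides nothing. Over the immediate early and dissociation stress list, fixed beforehand, limma's adjusted p for Dnajb1 was 0.138. All 8 lay higher after tamoxifen.

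Shared sequence of Hspa1a and Hspa1b and cell isolation were considered for the higher chaperone values. Probes shared by Hspa1a and Hspa1b could make a rise of 1 gene read in both, but could not create a rise by themselves. If the rise were confined to that pair, other chaperones would not move. The median of 16 chaperone genes not looked at before was 0.11 (0.069 to 0.19 without each single array), with 14 higher and Stip1 at 0.49 (0.33 without tamoxifen replicate 3). Of these, 1 had an unadjusted limma p under 0.05 and 0 passed when adjusted over the list alone. The 8 chaperones examined first were all higher, so this outcome could partly be foreseen. The median lay at percentile 99.97 among 10000 random lists of like level (99.43 to 99.98 without each single array). Such lists ignore that chaperones vary together (estimated correlation 0.325), and camera with an estimated correlation gave the 16 genes an unadjusted p of 0.239. The percentile therefore does not decide whether the rise was confined to the pair, though 14 of the 16 lay higher. The other 25 immediate early genes had a median of −0.010, percentile 58.54, with Jun at 0.49 (0.17 without control replicate 3) and Rgs2 at −0.54. Without control replicate 2 the percentile was 100, without tamoxifen replicate 1 99.92 and without control replicate 3 0.42, so isolation stays open, as do warming, tamoxifen itself and Sirt1 loss, which were not tested. SIRT1 is known to keep the heat shock factor HSF1 active, which alone would predict lower chaperone RNA.

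Il1b, Hp and Ifitm6 among the genes named lower, with Lyz2, Itgam and Ccr2, are genes of monocytes and granulocytes, and fewer monocytes carried through the sort may account for them. Of 24 monocyte genes not looked at before, 2 of them also in lists fixed earlier, the median was −0.088 and lay at percentile 0.18 of random lists of like level, but at 33.19, 5.62 and 56.13 without control replicate 1, tamoxifen replicate 2 and tamoxifen replicate 3. That leaves the explanation open, since 9 of the 24 lay higher, among them Clec4n (0.47, and 0.18 without tamoxifen replicate 2), the abundant Tyrobp and Fcer1g differed by 0.0030 and −0.14 (−0.064 to 0.091 and −0.27 to 0.0020 without each array), and camera with an estimated correlation gave an unadjusted p of 0.482. A lower level per cell and a change in neutrophils stay open, and no biological explanation from the design was tested.

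Cell cycle genes were higher in tamoxifen replicates 1 and 2 and lower in replicate 3, and nucleated erythroid precursors left in the sorted cells are a candidate source. Tamoxifen replicate 2 had the most erythroid RNA, with Car2 at 9.15 and Slc4a1 at 8.80, and without it the cell cycle list's camera adjusted p was 0.9921. It also had the highest cell cycle median, 0.62, so leaving it out shrinks the difference whatever the source. The call was lost without tamoxifen replicate 1 too (0.079, camera adjusted p = 0.303), so these losses do not point to erythroid cells. With the erythroid marker mean as a covariate, the adjusted p was 0.1173 and the list mean went from 0.19 (SE 0.37) to 0.060 (SE 0.22), so the call ended because the difference shrank, and it lay within the spread between arrays before and after. Over these alternatives and the others the adjusted p ranged from 7.22e-41 to 0.992. In tamoxifen replicate 1 the erythroid mean of 5.685 lay under the highest control, 5.814, while the cell cycle median was 0.45. Erythroid content gives no sign of having raised the cell cycle genes in that array. This rests on 1 array, so erythroid cells, other dividing cells and cycling B cells all stay open as sources.

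The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 0 genes past the threshold and the highest of the others 3, so all 10 splits gave as many. At an unadjusted p under 0.05 the real split gave 901 genes, 6 of the 10 splits gave as many, and the highest other gave 2698. That split sets control replicate 1 with tamoxifen replicates 1 and 3 against the rest. The splits that kept the Xist-high arrays, control and tamoxifen replicate 1, on the same side gave 1067, 1137, 1437 and 2698 genes. Every other split, the real one included, gave 565 to 1050. The counts thus point to a structure that these arrays share, whether sex or something else. The splits are therefore not a reference for chance alone. This was seen afterwards and not tested against what correlated genes give by chance. For gene lists the real split gave 13, the highest other 14, and 2 of the 10 splits gave as many.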
